A study of Mus musculus with 6 samples.

How the data were processed

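Mouse zygotes injected with a control siRNA (NC) or an siRNA against Eif4a3 were collected as blastocysts on day 5, per the labels. The series holds 3 libraries per group, each from a pool of 5 embryos, made with Smart-seq2 and sequenced as paired reads of 150 bases. Nothing in the labels says whether the pools of one group came from separate parents, so every p-value below measures only the spread between these samples. The labels give replicate numbers 1 to 3 in both groups. Across genes the correlation of same-numbered samples, after group means were removed, was 0.27, 0.00 and 0.10. NC replicate 2 correlated best with knockdown replicate 3 (0.19). The groups were therefore compared as unpaired, and a fit with the replicate number as a block is given as an alternative.

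Per the labels, the authors trimmed reads with fastp 0.20.1 after FastQC 0.11.9, aligned them with STAR 2.7.6a to GRCm38, counted with featureCounts 2.0.1 and used R 4.1.1 with DESeq2 1.34.0. Per the file headers, the authors counted read pairs per annotated exon with GENCODE vM29 moved to GRCm38 coordinates, so the deposited values are raw counts per exon line and not per gene. Every pair counted in each line that it overlapped, strand setting 2 was used, and the command gave no option to count pairs with several alignments. Because Smart-seq2 does not mark the strand, pairs whose orientation does not match this setting are missing from every count, and counts of genes that overlap another gene cannot be assigned to one of them. The count table has 842173 lines for 449500 distinct exons of 55378 genes, and 55102 of these were matched to a symbol.

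The planned tests assumed counts per gene. Exons that overlap within a gene were merged into 291424 blocks, the most counted line was kept for each block, and the blocks of a gene were summed. A pair that spans a splice junction counts in more than 1 block, so these sums are not numbers of sequenced pairs. They were 18389991, 15607226 and 16956944 for NC replicates 1 to 3 and 18617233, 16157715 and 18697761 for the knockdown replicates. Values per library are counts scaled to the effective library size (CPM, edgeR), and plus-minus values are standard deviations over 3 libraries. Summing all lines, and using only the most counted block of each gene, were alternatives.

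Genes were compared with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest with default settings, two-sided) under R 4.3.3. The p-values were adjusted by the Benjamini-Hochberg method over 15619 genes with a threshold of 0.05. Single values per library were compared with an exact two-sided permutation test, whose smallest p with n = 3 against 3 is 0.1. The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, among genes past the threshold with at least 10 CPM in a group and groups that did not overlap, the 12 with the largest rise and the 12 with the largest fall. Predicted or unnamed genes were left out of it (150 of 635 genes on the higher side, 33 of 667 on the lower). From each list up to 4 members with the smallest unadjusted p were taken, and the text gives some of them.

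The 34 lists cover exon junction complex factors, nonsense-mediated decay (NMD) factors, NMD target transcripts, SR and SR-related splicing regulators, core spliceosome, small nucleolar RNA (snoRNA) host genes, p53 targets, integrated stress response targets, apoptosis, autophagy and lysosome, trophectoderm, epiblast and inner cell mass, primitive endoderm, junctions with pumps and water channels, Hippo pathway, oocyte transcripts, 2-cell transcripts, mitosis, DNA replication, ribosome biogenesis, ribosomal proteins, histones, glycolysis, cholesterol synthesis, mitochondrial and nuclear oxidative phosphorylation, interferon-stimulated genes, sex-linked and intronless genes, eIF4A paralogs, and markers of cumulus, sperm, blood and fibroblast cells. The 30 lists with at least 5 tested genes were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Lists share members and are not independent. Gas5, Snhg1, Snhg12 and Snhg15 are NMD targets and snoRNA hosts, and Upp1 is an NMD target and an epiblast marker. The NMD target list also holds Atf4, Ddit3 and Chac1 (stress response), Srsf2, Srsf3, Srsf7 and Tra2b (SR regulators), and Smg5 and Upf3b (NMD factors). Targets of p53 include Bax, Bbc3, Pmaip1, Fas and Apaf1 (apoptosis) and Gdf15 and Sesn2 (stress response). Tead4 is in the trophectoderm and Hippo lists.

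A gene with 0 counts in NC was set against a floor of 3 counts over the 3 NC libraries and given as at least N-fold higher. A gene with 1 to 3 counts there was given as a ratio of pooled counts with its interval at a confidence level of 95%. Floors and intervals cover counting error alone.

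After the values were seen to be per exon, exon usage was added. Blocks were tested against the rest of their gene with diffSpliceDGE from edgeR, over 67890 blocks of 9494 genes, and per gene with the Simes method. With GENCODE vM21 on GRCm38, NMD exons were defined as internal exons that occur only in transcripts annotated to undergo NMD and overlap no other exon (1488 exons). Cassette exons were coding internal exons that another coding transcript skips (8684). Intron parts were the stretches of at least 100 bases that retained-intron transcripts add beyond coding exons, 1 per gene. The share of an exon was its count plus 0.5 over the count of its gene plus 1, on the log2 scale, for exons with at least 30.0 counts over the 6 libraries in genes with at least 50.0 in every library. The median share difference of the NMD exons was set against 10000.0 lists of cassette exons matched to their NC share and the mean count of their gene.

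The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, limma-voom with and without quality weights, upper-quartile scaling, glmTreat with a 1.5-fold threshold, no filter, a filter of 5 CPM in 3 libraries, the replicate block, removal of mitochondrial genes and the 20 most abundant genes, and each library left out in turn. Alternatives chosen after the data were seen were the other gene counts, offsets for GC content and length, removal of genes that overlap another gene by more than 20% of their exonic length, and all those for exon usage and exon shares. Intervals were merged with bedtools 2.31.1, and tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

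The fits were tested on simulated data whose spread followed the trend with count level in these libraries, without the scatter of single genes around it. Changes were placed only in better-counted genes and blocks, so the recovery does not apply to blocks with few counts. At an adjusted p under 0.05, 8 of 99 genes changed 2-fold and 64 of 98 changed 4-fold were recovered, with 3 calls among the unchanged of 14381 genes. Of 200 exon blocks changed 4-fold, 77 were recovered, with 8 calls among the unchanged blocks. With 3 libraries per group, many genes with 2-fold changes would therefore not pass.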

Results

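RNA was compared from pools of 5 mouse embryos that had received a control siRNA (NC) or an siRNA against Eif4a3 as zygotes and were collected on day 5, as blastocysts per the labels, with 3 libraries per group. Eif4a3 encodes the RNA helicase at the core of the exon junction complex, which marks spliced mRNA and, with NMD factors, leads to the decay of transcripts with an early stop codon.

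Eif4a3 RNA was lower in every knockdown library than in every NC library. It measured 253 ± 49.96 CPM in NC and 36.1 ± 20.1 CPM in the knockdown (16.03, 36.2 and 56.2 CPM), 7.002-fold lower (log2 fold change −2.81, standard error 0.44, adjusted p 0.00513 by edgeR, exact p 0.1 with n = 3). With only the most counted block, which is among the last 3, Eif4a3 had −1.52 (adjusted p 0.0403, where its alternatives ranged from 1.7e-08 to 0.0403). The gene lies on chromosome 11 (119288363 to 119300089, minus strand), and its remaining signal was uneven along the transcript. The 8 blocks nearest the 5′ end (from 119293559) went from 162 ± 43.8 to 6.66 ± 2.07 CPM, 24.4-fold lower. The 3 blocks nearest the 3′ end (up to 119292934) went from 90.6 ± 14.6 to 29.5 ± 19.9 CPM, 3.07-fold lower, and held 9.42%, 35.2% and 53.02% of the NC level in knockdown replicates 1, 2 and 3. In the exon usage test of edgeR 0 of the 11 blocks passed (lowest adjusted p 0.0998). Of the translation initiation helicases related to Eif4a3, Eif4a2 rose from 197 ± 23.6 to 380 ± 14.6 CPM (0.94, standard error 0.26, adjusted p 0.0409), a call lost when any 1 library was left out. Its adjusted p was then 0.132, 0.137 and 0.101 without NC replicates 1, 2 and 3, and 0.0567, 0.0903 and 0.0824 without knockdown replicates 1, 2 and 3. Eif4a1 did not pass (−0.32, adjusted p 0.479).

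**Figure D1:**
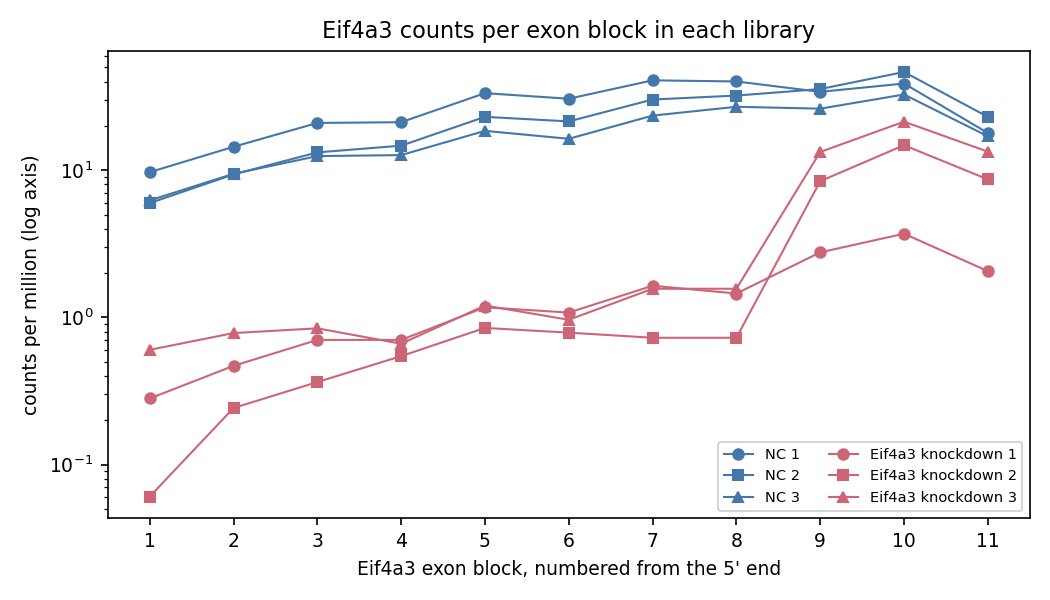
CPM of the exon blocks of Eif4a3, numbered from the 5′ end, on a log scale. Each line is 1 library, by group.

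RNA of the knockdown pools held transcripts that mouse embryos normally make in the burst of transcription at the 2-cell stage. These pools held less RNA of part of the marker genes of the blastocyst lineages and epithelium. At the preset correlation the lists of p53 targets, snoRNA hosts and cholesterol synthesis also shifted toward higher values, and those of DNA replication, mitosis and glycolysis toward lower values, in each case through part of their members. With an estimated correlation 0 of the lists passed. Primitive endoderm markers, p53 targets and NMD targets lost their calls although their estimates (0.0014, 0.0070 and 0.00245) lay under the preset 0.01. A high correlation between genes is therefore not what ended these calls. By edgeR, 1174 of 15619 genes were higher and 869 lower. In 1169 of the higher genes and 862 of the lower ones the groups did not overlap. This held for 36.4% of all genes tested, where chance gives 10% on average over splits. Genes vary together between libraries and the share was not computed for other splits, so its spread by chance is not known. Between libraries the correlation was 0.938 to 0.965 within NC, 0.921 to 0.941 within the knockdown and 0.818 to 0.883 between groups. The counts depended on single libraries, with 631 higher and 339 lower without NC replicate 1, 550 and 336 without NC replicate 2, 602 and 520 without NC replicate 3, 729 and 435 without knockdown replicate 2, and 819 and 427 without knockdown replicate 3.

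Of the 12 named genes with the largest rise, 8 are members of the 2-cell list, all of them Zscan4 or Usp17-like genes. Zscan4 genes encode SCAN domain zinc finger proteins that act on telomeres and mark the 2-cell stage, and Usp17-like genes encode deubiquitinases. Against a floor of 3 counts over the 3 NC libraries, which all held 0, Usp17le was at least 244-fold higher (14.8 ± 5.27 CPM in the knockdown), Lrrc69, a leucine-rich repeat gene, at least 201-fold (11.96 ± 0.252 CPM), the expressed sequence AA792892 at least 186-fold (11.3 ± 4.02 CPM), the olfactory receptor gene Olfr376 at least 172-fold (10.7 ± 5.41 CPM) and Zscan4b at least 162-fold (10.4 ± 12.3 CPM). With 1 or 2 NC counts in all, the ratio and its counting interval were 1511 (418 to 12485) for Zscan4c (9.37, 58.0 and 127 CPM in knockdown replicates 1, 2 and 3), 1506 (270 to 59511) for Usp17lb (29.8 ± 14.3 CPM), 1154 (207 to 45620) for Zscan4a (23.9 ± 11.9 CPM), 1054 (291 to 8710) for Zscan4d (44.3 ± 30.5 CPM) and 260 (71.7 to 2153) for Usp17la (10.7 ± 3.99 CPM). Zscan4f was 378-fold higher (33.4 ± 15.7 CPM in the knockdown) and the expressed sequence BB287469 175-fold (17.3 ± 11.6 CPM). Adjusted p ranged from 0.000752 (Usp17lb) to 0.009 (Zscan4b). The Zscan4 and Usp17-like genes lie in near-identical copies on chromosome 7, where pairs with several alignments were not counted, so their levels and the split between copies are uncertain.

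Of the 25 members of the 2-cell list 21 were tested, of which 19 were higher, 0 lower and 2 did not pass (20 higher when adjusted over the list alone). A gene with 0 counts in NC enters the tests only through the knockdown, and could then only be higher. The near-identical copies were counted as separate members. Its median log2 fold change was 7.27, or 7.14 with members at 0 in NC set to their bounds (camera adjusted p 1.1e-32, adjusted p = 0.115 with an estimated correlation). Of 34 oocyte and maternal-effect transcripts 20 were tested, with 5 higher and 1 lower (8 and 2 over the list alone). Their median was 1.23 and the camera adjusted p 0.0221 (adjusted p = 0.592 with an estimated correlation). The call of that list was lost without knockdown replicates 2 (0.0624) or 3 (0.0791), with fry (0.145) and with the most counted block (0.487), and under the filter of 5 CPM the list turned toward lower values (0.899). Obox1, an oocyte homeobox gene with 0 NC counts, was at least 27.5-fold higher (adjusted p 0.00905). Oosp1, which encodes a secreted oocyte protein, was at least 15.7-fold higher (0.0132), a call lost without NC replicate 2 (0.0545) or knockdown replicate 2 (0.0504). Ooep, a part of the subcortical maternal complex, was lower (−1.80, adjusted p 0.0296), a call lost without NC replicates 2 (0.0822) or 3 (0.0810) or knockdown replicate 2 (0.0622).

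The 12 named genes with the largest fall include 2 lineage markers of the fixed lists. Tdgf1, the NODAL coreceptor of the epiblast, went from 182 ± 59.0 to 5.03 ± 1.84 CPM, 36.1-fold lower (−5.18, standard error 0.44, adjusted p 0.000752). Pdgfra, the growth factor receptor of primitive endoderm, went from 11.2 ± 4.23 to 0.499 ± 0.432 CPM (−4.50, adjusted p 0.00724). Also lower were Cnn2, which encodes the actin-binding protein calponin 2 (−4.85, 149 ± 163 to 5.16 ± 2.11 CPM, adjusted p 0.00552), Myl9, a myosin light chain gene (−4.64, 0.0134), and Myo1d, an unconventional myosin gene (−4.59, 0.00276). Others were P2rx3, an ATP-gated channel (−4.57, 0.00504), Susd2, a sushi domain protein (−4.45, 0.00287), and the water channel Aqp8 (−4.46, standard error 1.15, 0.0316). Fam25c (−5.35, 0.00558), the protease inhibitor gene Serpinb6b (−4.95, 0.0101), Ube2l6, which conjugates ISG15 (−4.65, 0.00416), and the glycosyltransferase gene B3gnt7 (−4.47, 0.0160) complete the 12. The Aqp8 call was lost without NC replicates 1 (0.0828) or 3 (0.0725) or knockdown replicates 1 (0.0589) or 3 (0.0588), and its log2 fold change was −7.56 without knockdown replicate 2. The B3gnt7 call was lost without NC replicate 3 (0.0536) or knockdown replicate 3 (0.0526). With 1 library left out, Myl9 ranged from −5.76 to −3.44, Cnn2 from −5.28 to −3.42 and P2rx3 from −4.99 to −3.44. These 3 kept their calls.

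The marker lists of all 3 blastocyst lineages shifted toward lower values at the preset correlation, in each case through part of their members. Of 23 epiblast and inner cell mass markers 0 were higher and 8 lower (11 lower over the list alone), with a median of −0.80 (camera adjusted p 2.4e-08, adjusted p = 0.173 with an estimated correlation). Upp1, a uridine phosphorylase, fell from 252 ± 25.1 to 37.3 ± 5.03 CPM (−2.75, adjusted p 0.000954), the chromatin-bound pluripotency factor Utf1 had −2.48 (0.00362) and the secreted phosphoprotein Spp1 −4.16 (0.00535). The pluripotency factors Nanog (−0.91, 0.155) and Pou5f1 (−0.62, 0.293) did not pass. Of 17 primitive endoderm markers 0 were higher and 6 lower (7 over the list alone), with a median of −0.97 (1.4e-05, adjusted p = 0.115 with an estimated correlation). Among them were the basement membrane genes Sparc, from 182 ± 13.6 to 11.6 ± 4.81 CPM (−3.97, 0.000752), and Lamb1 (−2.19, 0.0105), and the factor Gata6, which did not pass (−0.12, 0.794). Of 22 trophectoderm markers 1 was higher and 10 lower (1 and 16 over the list alone), with a median of −1.69 (8.0e-07, adjusted p = 0.346 with an estimated correlation). The endocytic receptor Lrp2 fell from 504 ± 160 to 65.1 ± 15.9 CPM (−2.95, 0.00188) and the T-box factor Eomes had −2.77 (0.00629), while the imprinted cell cycle inhibitor Cdkn1c was higher (2.97, 0.00537). Exons of another gene overlap 30.7% of Cdkn1c. Cdx2, the trophectoderm homeobox factor, did not pass (−1.82, 0.0676).

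Of 29 genes of the epithelium around the blastocyst cavity, 0 were higher and 12 lower (1 and 19 over the list alone). Their median was −1.38 and the camera adjusted p 9.4e-09 (adjusted p = 0.327 with an estimated correlation). The gap junction gene Gjb5 fell from 79.0 ± 16.9 to 14.1 ± 2.26 CPM (−2.48, adjusted p 0.00217). The membrane linker Ezr (−2.29, 0.0115) and the adhesion protein gene Cdh1 (−1.61, 0.01) were also lower. In the Hippo pathway, which separates trophectoderm from inner cells, 1 of 19 genes was higher and 2 were lower (1 and 2 over the list alone), with a median of −0.96 (0.0332, adjusted p = 0.322 with an estimated correlation). That call was also lost with fry (0.0668) and under the filter of 5 CPM (0.359). The DNA-binding partner of YAP, Tead1, was lower (−3.41, 0.0141) and the scaffold gene Sav1 higher (2.43, 0.00607), with 25.4% of Sav1 overlapped by another gene.

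Of 28 targets of p53, 9 were higher and 0 lower (10 over the list alone). Their median was 0.67 and the camera adjusted p 8.3e-05 (adjusted p = 0.115 with an estimated correlation). The death receptor gene Eda2r rose from 41.6 ± 8.89 to 188 ± 51.1 CPM (2.18, adjusted p 0.0043) and the stress protein gene Trp53inp1 rose by 1.95 (0.00476). Ccng1, a cyclin gene (1.49, 0.00804), and Mdm2, which encodes the ligase that degrades p53 (1.57, 0.0124), lost their calls without NC replicate 2 (0.0522) and NC replicate 1 (0.0532). The cell cycle inhibitor Cdkn1a did not pass (0.78, 0.114). Apoptosis machinery had 2 of 22 higher and 0 lower (2 over the list alone), with a median of −0.23, a mean of 0.08 and a camera test toward lower values (0.800). Of 23 tested targets of the integrated stress response 4 were higher and 2 lower (5 and 2 over the list alone), with a median of 0.18 (0.800). Among them Ddit3, a factor of stress-induced death that is also in the NMD target list, was higher (20.8 to 83.2 CPM, 0.00704). Autophagy and lysosome genes had 6 of 33 higher and 2 lower (6 and 2 over the list alone). Their median was −0.22, their mean 0.01 and the camera test toward lower values (0.910), with the autophagy genes Atg9b higher (3.37, 0.00432) and Atg13 lower (−1.91, 0.0082).

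Of 19 established NMD target transcripts, 7 were higher and 2 lower (8 and 3 over the list alone), with a median of 0.95. The list shifted toward higher values by camera (adjusted p 0.0342, adjusted p = 0.276 with an estimated correlation). Upp1, named above among the epiblast markers, was 1 of the 2 lower members. The snoRNA host genes, whose spliced transcripts are NMD substrates, had 6 of 15 higher and 0 lower (7 and 1 over the list alone), with a median of 0.81 (3.0e-04, adjusted p = 0.559 with an estimated correlation), which was 0.25 with offsets for GC content and length. Snhg17 rose from 18.4 ± 1.36 to 232 ± 68.3 CPM (3.65, standard error 0.33, adjusted p 0.000752), Snhg15 from 44.1 ± 19.1 to 512 ± 126 CPM (3.54, 0.00166), Snhg5 by 2.58 (0.00257) and Snhg1 by 2.38 (0.00644), with 20.9% of Snhg1 overlapped by another gene. No partner of Eif4a3 in the exon junction complex passed (0 of 11 higher or lower, also over the list alone, median −0.15, 0.800). Of these, the export helicase Ddx39b had −0.65 (0.180) and the core subunit gene Rbm8a 0.57 (0.344). NMD factors had 0 of 12 higher or lower, also over the list alone, with a median of −0.34 (0.532), and the NMD helicase Upf1 had −1.70 (0.103).

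Splicing regulators of the SR group had 2 of 18 higher and 1 lower (2 and 1 over the list alone), with a median of −0.04 (0.910). The kinase gene Clk4 was higher (1.35, adjusted p 0.0201), a call lost without NC replicates 1 (0.0815) or 2 (0.0929) or knockdown replicate 2 (0.0594). The SR-related protein gene Srrm2 was lower (−1.35, 0.0214), a call lost without NC replicates 1 (0.0551) or 2 (0.0848) or knockdown replicate 3 (0.0639). Of the core spliceosome 1 of 36 genes was higher and 5 were lower (1 and 5 over the list alone), with a median of −0.32 and a camera adjusted p of 0.125, which was 0.04997 without NC replicate 3. Prpf8, at the centre of the spliceosome, was lower (−1.66, 0.0121), and the 3′ splice site factor U2af1 higher (1.37, 0.0136), a call lost without NC replicates 2 (0.0641) or 3 (0.0583).

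Of 22 genes of cholesterol synthesis, 9 were higher and 0 lower (14 over the list alone). Their median was 1.18 and the camera adjusted p 9.0e-07 (adjusted p = 0.123 with an estimated correlation). Cyp51, the sterol demethylase, rose from 59.1 ± 23.0 to 327 ± 73.3 CPM (2.47, adjusted p 0.00471), and the sterol sensor partner Insig1 (2.03, 0.00317), the sterol oxidase Msmo1 (1.70, 0.00681) and the desaturase Sc5d (1.85, 0.00776) were higher too. Glycolysis had 0 of 19 higher and 4 lower (1 and 10 over the list alone), with a median of −1.14 (2.6e-04, adjusted p = 0.375 with an estimated correlation). The pyruvate kinase gene Pkm was lower (−2.91, 0.0132), a call lost without knockdown replicate 2 (0.0583). Nuclear genes of oxidative phosphorylation had 0 of 73 higher and 2 lower (1 lower over the list alone), with a median of −0.39 (2.6e-04, adjusted p = 0.668 with an estimated correlation), and the complex II gene Sdha was lower (−1.97, 0.0108).

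DNA replication genes had 2 of 35 higher and 11 lower (3 and 13 over the list alone), with a median of −0.73 (camera adjusted p 2.2e-04, adjusted p = 0.123 with an estimated correlation). Mcm4, a subunit of the replicative helicase, fell from 140 ± 10.02 to 44.5 ± 6.62 CPM (−1.65, adjusted p 0.00566). Mitosis genes had 0 of 28 higher and 3 lower (3 lower over the list alone), with a median of −0.42 (0.00174, adjusted p = 0.559 with an estimated correlation), among them the topoisomerase Top2a, from 101 ± 22.6 to 23.6 ± 1.73 CPM (−2.10, 0.00373). Ribosome biogenesis factors had 2 of 39 higher and 2 lower (2 and 1 over the list alone), with a median of −0.16 (0.643), and the rRNA methylase gene Fbl was higher (1.75, 0.00959). Ribosomal protein genes had 1 of 88 higher and 1 lower (1 and 1 over the list alone), with a median of −0.03 (0.910), and without NC replicate 1 the list passed toward lower values (0.0013). In it Rpl10l, an intronless paralog, was higher (1.96, 0.00471) and Rps24 lower (−2.11, 0.0141).

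Together 15 of 30 lists passed with camera, 6 toward higher and 9 toward lower values, while 0 passed with an estimated correlation between genes (6 at an unadjusted p under 0.05) and 7 with fry. Other splits of the libraries into equal groups gave 8 to 16 lists with camera, so the number of lists does not set the real groups apart. The calls that fry ended were those of the trophectoderm (0.0713), epithelium (0.0565), Hippo (0.0668), oocyte (0.145), mitosis (0.0756), glycolysis (0.0565), oxidative phosphorylation (0.329) and snoRNA host (0.0828) lists. Of the lists not described above, interferon-stimulated genes had 0 of 9 higher and 2 lower (2 lower over the list alone), with a median of −0.33 (0.378). Histone genes had 1 of 40 higher and 0 lower (0 over the list alone), with a median of 0.17 (0.910). Mitochondrially encoded genes had 0 of 12 higher or lower, also over the list alone, with a median of 0.03, a mean of 0.17 and a camera test toward lower values (0.910). Sex-linked transcripts had 0 of 5, also over the list alone, with a median of 0.89 (0.414), and intronless genes 134 of 1716 higher and 37 lower (118 and 28 over the list alone), with a median of 0.07 (0.414). Blood markers had 0 of 7 higher and 2 lower (4 lower over the list alone), with a median of −1.88 (0.0720). That list passed toward lower values without NC replicates 1 (0.0424) or 3 (0.00142) or knockdown replicate 3 (0.0417). Markers of cumulus, fibroblast and sperm cells had 1, 3 and 0 genes tested, too few for a test.

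**Figure D2:**
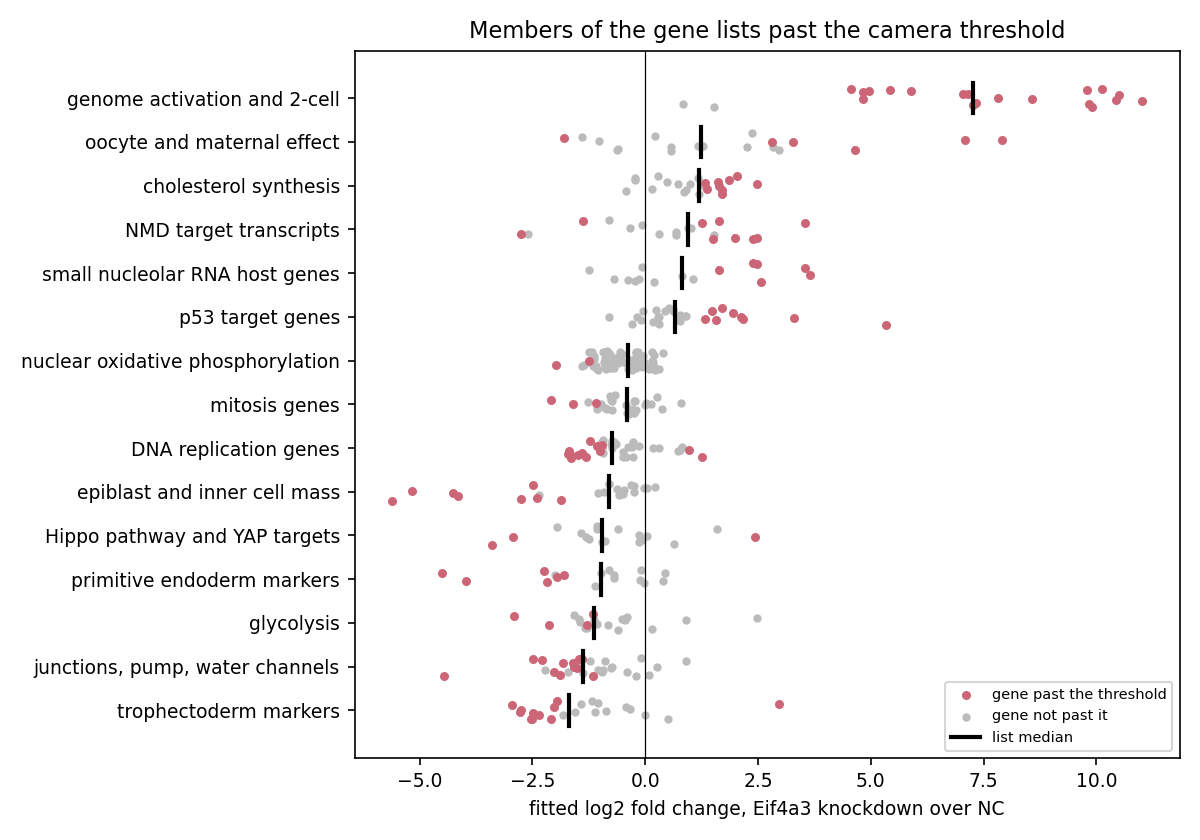
Log2 fold change of the members of the 15 gene lists that passed with camera at the preset correlation. Dots are genes and bars are medians.

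**Figure D3:**
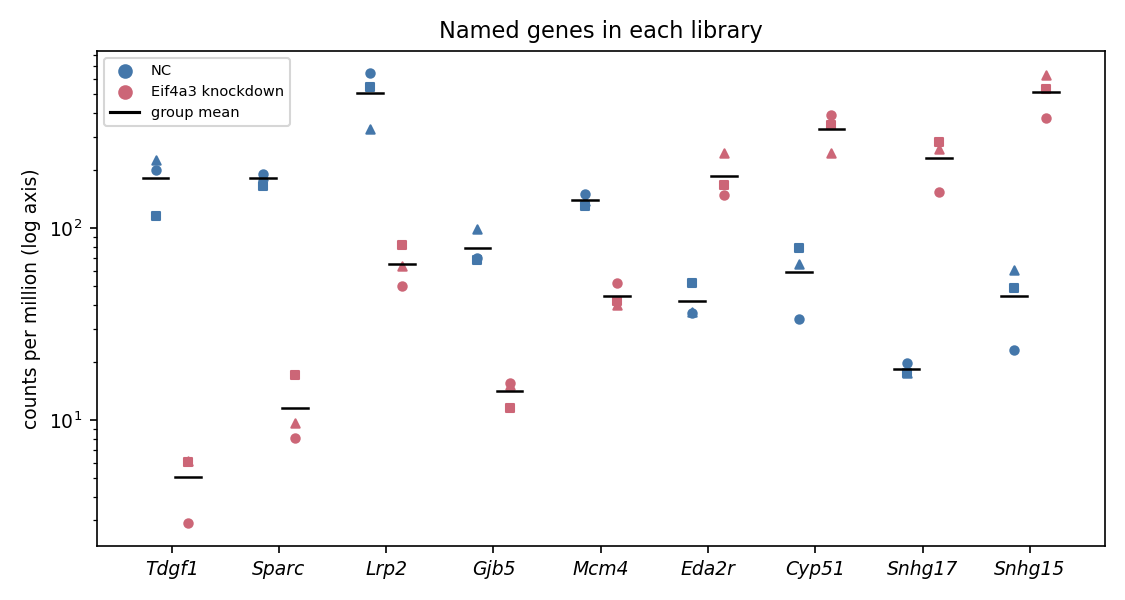
CPM of 9 genes in each library, on a log scale. Circles, squares and triangles are replicates 1, 2 and 3, and colours are the groups.

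Genes with at least 1 count numbered 22556 ± 554 in NC and 24003 ± 709 in the knockdown, and 22370 and 23709 after thinning to equal totals (exact p 0.1, adjusted p 0.3 over 6 measures). Genes with at least 10 counts numbered 14743 ± 273 and 15992 ± 344 (0.1, adjusted 0.3). Mitochondrial genes held 1.63 ± 0.285% and 1.98 ± 0.658% of counts (exact p 0.7), the 100 most abundant genes 23.8% and 23.6% (0.8), and ribosomal protein genes 6.23% and 6.48% (0.9).

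Exons found only in transcripts annotated to undergo NMD took a larger share of their genes in the knockdown. Of 99 blocks with such exons in the exon usage test 16 were higher (16.2%) and 0 lower. Of 1414 cassette blocks 7 were higher (0.495%) and 1 lower, and of 66377 other blocks 61 were higher (0.0919%) and 29 lower. The filter of this test admits blocks counted mainly in the knockdown, such as that of Xpa, with 0, 3 and 1 counts in NC. Cassette blocks were not matched on share, so the difference between these percentages may in part reflect which blocks could enter. The NMD exon of Cystm1, which encodes a small membrane protein, went from 0.0855 ± 0.0428% to 2.11 ± 0.897% of its gene (adjusted p 3.6e-04), that of the excision repair gene Xpa from 0.495 ± 0.571% to 10.5 ± 2.58% (3.6e-04), that of Psmd11, a proteasome lid subunit, from 0.0391% to 0.460% (3.9e-06) and that of the recombination gene Swi5 from 0.0710% to 1.02% (1.5e-04). In all, 114 blocks changed their share of the gene (84 higher, 30 lower), in 86 genes by the Simes test. Blocks at an unadjusted p under 0.05 numbered 1690 of 67890, fewer than chance alone would give at that threshold. Of the 114, 21 lay in genes whose total also changed. The groups did not overlap in any of the 114. Other blocks included 1 of Emd, which encodes emerin of the nuclear envelope (chromosome X, 74260782 to 74261548), from 0.642% to 6.80% (2.4e-06). A block of Btbd1 (chromosome 7, 81800385 to 81800493) went from 0.391% to 5.605% (2.4e-06). Exons named here were chosen after their values were seen. The count was 21 without NC replicate 1, 22 without NC replicate 2, 34 without NC replicate 3, and 45 and 63 without knockdown replicates 2 and 3, and it was 8 under the filter of 5 CPM.

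Across 172 NMD exons of 159 genes the median share was 0.465% in NC and 1.39% in the knockdown. The median log2 difference was 1.49 (quartiles 0.50 and 2.26), and 147 exons (85.5%) were higher. The minimum of counts over all 6 libraries admits exons seen mainly in the knockdown. For 103 exons with at least 15 counts in NC alone the median was 0.75 and 72.8% were higher. Cassette exons chosen likewise, which were not matched on share, had a median of 0.02. Lists of cassette exons matched to the 172 had medians around 0.61 when matched on NC share and 0.28 when matched on the share over all 6 libraries. The groups did not overlap toward higher shares in 98 exons (57.0%) and toward lower shares in 5 (2.91%), where chance gives 5% in each direction, and cassette exons had 14.7% and 9.60% and intron parts 8% and 17.2%. The median share was 0.448%, 0.391% and 0.416% in NC replicates 1 to 3 and 1.51%, 1.32% and 1.11% in the knockdown (exact p 0.1 with n = 3, adjusted p 0.3). Overlapping exons share counts, and the 170.0 exons with distinct counts had a median of 1.47. Across 1948 cassette exons, which coding transcripts skip or include, the median difference was 0.05 (exact p 0.4). Across 425 intron parts, which measure retained introns, it was −0.42 (exact p 0.4).

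**Figure D4:**
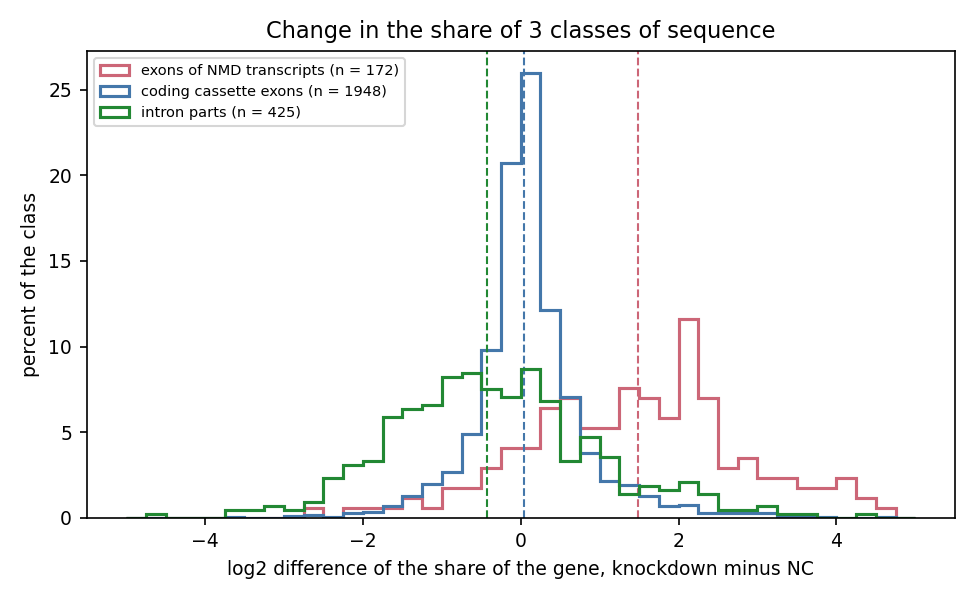
Log2 difference in share of the gene between knockdown and NC for NMD exons, cassette exons and intron parts. Dashed lines are medians.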

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

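The other gene counts, the GC and length offsets, the removal of overlapping genes, and every alternative for exon usage and exon shares were chosen after the data were seen. Of 98 named genes that passed, 57 kept the call under every alternative run, 41 lost it with some library left out, and 0 changed direction while called. DESeq2 size factors kept 98 of the 98, DESeq2 97, voom 96, upper-quartile scaling 95, and the GC and length offsets 94. The most counted block kept 87 of 92, and removal of overlapping genes 93 of 93. Of the genes that did not pass, Magohb changed direction with the offsets (−0.19).

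The number of higher and lower genes was 2089 and 1518 without a filter, 1897 and 1415 with DESeq2 over 19907 genes, and 713 and 382 with glmTreat, and 495 genes were lower with all lines summed. A filter sets which genes are tested, DESeq2 sets its own, and glmTreat asks for more than a 1.5-fold change. For the summed lines the cause was not tested. With 1 library left out the range was 550 to 1223 higher and 336 to 1131 lower, and Eif4a3 had −3.29 to −2.49. With only the most counted block Eif4a3 had −1.52. With the replicate number as a block, 1332 genes were higher and 1198 lower.

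The 15 lists became 0 with an estimated correlation, 7 with fry and 14 to 17 with 1 library left out. Fry asks whether the members of a list shift in the same direction, without comparison with other genes. In the following the adjusted p is given for lists whose direction turned under some alternative, and the cause was not tested. The oocyte list lost its call and turned under the filter of 5 CPM (0.899), where its alternatives ranged from 3.4e-05 to 0.899. SR regulators turned with fry (0.976), the filter (0.914) and without knockdown replicate 2 (0.956), with 0.604 to 0.956 over the 6 fits that leave out 1 library. Stress response targets turned with the filter (0.839) and without knockdown replicate 1 (0.456, of 0.411 to 0.908 over the 6 fits). Autophagy turned with fry (0.976), the filter (0.852) and without knockdown replicates 2 (0.994) or 3 (0.604), of 0.390 to 0.994. Interferon-stimulated genes turned without NC replicate 3 (0.979, of 0.328 to 0.979). Mitochondrially encoded genes turned with fry (0.976), the filter (0.949), the most counted block (0.883), and without NC replicate 3 (0.820) or knockdown replicate 1 (0.466), of 0.180 to 0.866. Ribosomal protein genes turned with fry (0.976), the filter (0.899), the most counted block (0.867), and without NC replicates 2 (0.912) or 3 (0.223) or knockdown replicate 1 (0.163), while the lowest of their 6 fits (0.0013) kept the direction. Histone genes turned with the replicate block (0.942), the filter (0.459), and without NC replicate 1 (0.184) or knockdown replicates 2 (0.705) or 3 (0.376), of 0.184 to 0.866.

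With the GC and length offsets, list medians that turned or moved by more than 1.5 times were those of snoRNA hosts (0.25), nuclear oxidative phosphorylation (−0.74), NMD factors (−0.06), ribosomal proteins (−0.30), SR regulators (−0.15), autophagy (−0.10), interferon-stimulated genes (−0.16), mitochondrially encoded (−0.82), histone (−0.30), sex-linked (0.58) and intronless genes (−0.24) and eIF4A paralogs (0.15).

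The 114 exon blocks became 8 with the filter of 5 CPM, 174 with the replicate block and 21 to 155 with 1 library left out. The gene-wise F test gave 282 genes with changed usage where the Simes test gave 86, and the cause was not tested. The median difference of the NMD exons was 1.31 with at least 10 counts per exon, 1.03 with a pseudocount of 2, which pulls low shares together, 0.75 with exons chosen on at least 15 counts in NC alone, which leaves out exons seen mainly in the knockdown, and 1.40 to 1.62 with 1 library left out.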

Other observations

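Genes not typed as protein-coding were more frequent among the higher than among the lower genes. Of the higher genes 829 (70.6%) were protein-coding, against 816 (93.9%) of the lower genes and 81.0% of all genes tested. Long intergenic RNAs numbered 107 among the higher and 4 among the lower genes, processed pseudogenes 53 and 7, and antisense RNAs 47 and 16. This was seen in the tables and no test of it was planned or made. Shorter genes and genes of lower GC content tended to be higher (Spearman correlations −0.14 and −0.13 with the log2 fold change), and the antisense count is uncertain, because the libraries do not mark the strand.

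The tests of earlier-stage embryos and of multicopy families for the 2-cell transcripts, of unspliced RNA and of a few genes for the NMD exons, and of a general shift of coverage and of 1 cleavage site for Eif4a3 were chosen after the result was seen. The real split of the 6 libraries gave 2043 changed genes, 15 lists and 114 exon blocks, and the highest of the other 9 splits gave 0, 16 and 0. As large a count as the real one came from 1, 4 and 1 of the 10 splits, the real one included. For genes and exon blocks, 10 splits are too few for a share under 0.05. For lists, the other splits gave 8 to 16 with 0 changed genes, so the number of lists does not set the real split apart.

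Transcripts of the 2-cell list were higher in the knockdown, with a median of 7.27 over the 21 members tested. Bias from GC content and gene length as the whole of it is argued against by the median of 6.79 with offsets for both. Reads shared among gene families as the whole of it are argued against by single-copy members, since Zfp352 (0.0219 ± 0.0379 and 4.20 ± 3.27 CPM, adjusted p 0.00522) and Tmem92 (4.83, 0.0044), 2 of the 3 tested, passed, and Arg2 did not (1.53, 0.0511). Embryos arrested at or delayed from an earlier stage may contribute, and 5 of 20 tested oocyte list members being higher neither shows nor excludes them. Renewed transcription of these genes after the loss of Eif4a3 could not be told apart from such embryos, because each library is a pool of 5.

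Exons of NMD transcripts were higher in share, with a median of 1.49, or 0.75 for exons chosen on their NC counts alone. A general rise of unspliced RNA as the whole of it is argued against by intron parts, which had a median of −0.42 (exact p 0.4, groups overlapping). These parts lie beside coding exons of 425 genes, so unspliced RNA around the NMD exons themselves was not measured. For the 172 exons behind the 1.49, a general rise of weakly included exons as the whole is argued against by matched cassette exons. Lists of these, chosen in the same way, had medians around 0.61 with an upper bound of 0.76 when matched on NC share. Matched on the share over all 6 libraries, the medians lay around 0.28. No matched lists were drawn for exons chosen on NC counts alone. For their median of 0.75 this explanation was therefore not tested. A few genes as the source are argued against by exons chosen on NC counts alone, of which 72.8% were higher. Cassette exons chosen likewise had 52.6%, but were not matched on share. The measure set for a few genes was that the groups did not overlap toward higher shares. This held in 57.0% of all NMD exons, against 14.7% of cassette exons. That comparison cannot decide, because the filter admits NMD exons seen mainly in the knockdown and the cassette exons were not matched on share. A candidate explanation is slower decay of these transcripts when less exon junction complex is laid down, and changed splicing that makes more of them stays open, as does a stage difference between the groups, which was not tested.

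The last 3 exon blocks of Eif4a3 kept more signal than the first 8 in the knockdown, though 0 of the 11 passed the exon usage test (lowest adjusted p 0.0998). A general shift of coverage toward 3′ ends is argued against by the position index over 3411 genes, where 0 of 3 knockdown libraries lay above every NC library. Pairs from Eif4a3-like retrogenes stay open, since their own counts reached 22.8%, 4.92% and 13.0% of those of the most counted 3′ block in knockdown replicates 1, 2 and 3. Cleavage at 1 site, with the 3′ part outlasting the 5′ part, stays open too. The residual sum of squares of 1 step along the blocks was 0.0696 of that of a line for the mean of the knockdown libraries (0.353, 0.383 and 0.142 for replicates 1, 2 and 3), which restates the pattern and does not test its cause.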
